A study of Caenorhabditis elegans with 2 samples.

How the data were processed

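The samples were whole hermaphrodite young adults of the nematode Caenorhabditis elegans, collected 67 hours after synchronisation as starved L1 larvae. The strain carries a transgene in which MXL-1, a Max-like basic helix-loop-helix leucine zipper protein, bears a C-terminal tag of GFP and FLAG, and an unc-119 mutation, per the labels. Chromatin bound by the tagged protein was collected with an antibody against GFP and sequenced (ChIP-seq). There were 2 biological replicates, per the labels, and both belong to 1 group, so no comparison between conditions could be made. Strain, stage and antibody were the same in both.

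The deposited files were peak lists in the narrowPeak format, each given on the genome builds ce10 and ce11. Per the deposited file descriptions, there was 1 list for each replicate, 1 called on the pooled alignments and 1 thresholded list. The thresholded list is labelled as set by the authors' test of reproducibility between replicates (irreproducible discovery rate). The pooled list is labelled as peaks and background used as input for that test, so its weaker entries need not be binding sites. The aligner, the peak caller and their versions are not given in the sources used here. The deposited peak signal has no stated scale, so it was used only to rank and describe peaks within a list. The authors' −log10 q value was the same for every thresholded peak and was not used to rank. In both builds the thresholded list was the top of the pooled list by signal, 557 of 557 peaks in ce11 and 531 of 531 in ce10. It is thus a cut by signal, and a single peak in it need not have a match in both replicates. A further source file that the descriptions list without saying what it holds, and the control experiment that the labels name as possible, were not used here. Read totals were not used here, so the depth of each sample is unknown, and the exact (Clopper-Pearson) 95% intervals given for shares cover the counting of peaks, genes or sites only.

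Genes were taken from Ensembl release 115 and sequence from RefSeq, both on WBcel235, the assembly that ce11 names. No peak end in the ce11 lists exceeded the length of its chromosome. All positions are 1-based ce11 coordinates, ce10 lists served only for the overlap of replicates and for counts per chromosome, which were set against the gene shares of the ce11 annotation, and no coordinate was converted. A promoter window ran from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start. Separately from promoter windows, every summit was given 1 of the position classes coding exon, 5'UTR, 3'UTR, intron and outside protein-coding genes. Names of tRNA families came from the RefSeq annotation, which named 607 of the 612 nuclear tRNA genes.

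Chance levels for positions and for the overlap of replicates came from circular shifts of the summits within each chromosome, 10000 for the reported values and 1000 under the alternatives, with two-sided permutation p-values whose smallest possible values are 0.0002 and 0.002. Summits of different lists within 100 bp were counted as shared. Sequence was read 100 bp either side of each summit and compared with windows of the same size centred 1000 bp away, by exact McNemar tests for single sequences against the lower flank and by Fisher's exact test for all 2080 strand-collapsed 6-mers against both flanks. Signal was compared by permutation tests of mean ranks with 100000 resamples. Chromosome counts were compared with the share of protein-coding genes by exact binomial tests. The 28 gene lists were fixed before the data were examined as patterns on gene symbols, and their bound shares were compared with those of all other nuclear protein-coding genes by Fisher's exact test. All tests were two-sided, the threshold was 0.05, and Benjamini-Hochberg adjustment was made over the 6-mers, chromosomes, lists or tRNA families. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

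The rule for named genes, fixed before the data were examined, took the 20 strongest thresholded peaks with their nearest protein-coding transcript start, every member of the Max network list, mxl-1 and unc-119, the 4 strongest bound members of each list past the threshold and up to 2 of every other list. The 7 mitochondrial peaks among the 20 have no nuclear promoter and are named by the mitochondrial gene at the peak. Genes outside this rule are said to have been chosen after their values were seen. The split of peaks by a tRNA, snoRNA, snRNA or rRNA gene within 250 bp of the summit, called small RNA genes below, was chosen after the strongest peaks had been seen, and so were all tests that use it, the tests of GTTCGA, the tRNA families and the comparisons of X with the autosomes. Motifs, 6-mers, positions, chromosomes and gene lists were each examined over all peaks and without peaks at small RNA genes, and motifs, 6-mers and positions also over the peaks at small RNA genes alone.

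The tests were checked on simulated data. With CACGTG planted in 20% of windows at random genome positions it ranked 1 of 2080 6-mers, and 0 6-mers passed without it. When promoters were bound at random, the first draw called 1 of the 28 lists by chance, and 5 of 200 further draws (2.50%) called any list. With 1 list bound at 25%, that list was called along with the chance call. The planted shares exceed those found below for CACGTG and for the lists, so detection at smaller shares was not checked. Random summits at tRNA genes gave a permutation p of 0.963 and planted ones 0.002. Alternatives fixed before the data were examined were other matching distances, window sizes, promoter windows, control sets, backgrounds and expected shares, the 275 stronger nuclear peaks of the thresholded list, the other build, and the top 557 peaks of either replicate alone. Distances of 100 and 500 bp from small RNA genes and the sets without peaks at them were added after seeing the data.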

Results

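Binding of the GFP-tagged transcription factor MXL-1 was mapped by ChIP-seq in 2 biological replicates of whole young adult worms. MXL-1 is the partner of MDL-1 in the worm's Max network, whose dimers bind the E-box CACGTG. The ce11 lists held 20313 peaks in replicate 1, 21882 in replicate 2, 14200 in the pooled list and 557 in the thresholded list, which is the set described here unless another is named. Of these 557 peaks, 550 were nuclear. The pooled list is labelled as peaks and background, so the weaker pooled peaks below are entries of that list and need not be binding sites. The signal of each peak is the authors' value, and depth per sample is unknown.

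The first question was how far the replicates shared peaks. Of the 557 strongest peaks of replicate 1, 285 (51.2%) had a summit within 100 bp of one of the 557 strongest of replicate 2, against a mean of 0.243% after circular shifts (permutation p = 0.0002, the smallest the shifts can give). Sharing was more frequent at small RNA genes, at 203 of 303 replicate 1 peaks (67.0%, 95% interval 61.4 to 72.3), than elsewhere, at 76 of 248 (30.6%, 24.97 to 36.8; Fisher's exact p = 1.19e-17). These classes were not matched for signal. Sharing also varied with peak strength, at 61.9% of the 278 strongest peaks and 40.6% of the 1114 strongest. Of the thresholded peaks, 520 (93.4%) had a matching peak of any strength in both replicates. The matches reached down to rank 14355 in replicate 1 and 7695 in replicate 2, and no chance level was computed for them. Among the 557 strongest peaks, 410 had a match in replicate 1, 415 in replicate 2 and 295 in both. Spearman's rho of the signal over the 514 matched nuclear peaks was 0.427, a description across peaks, which are not independent replicates.

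**Figure D1:**
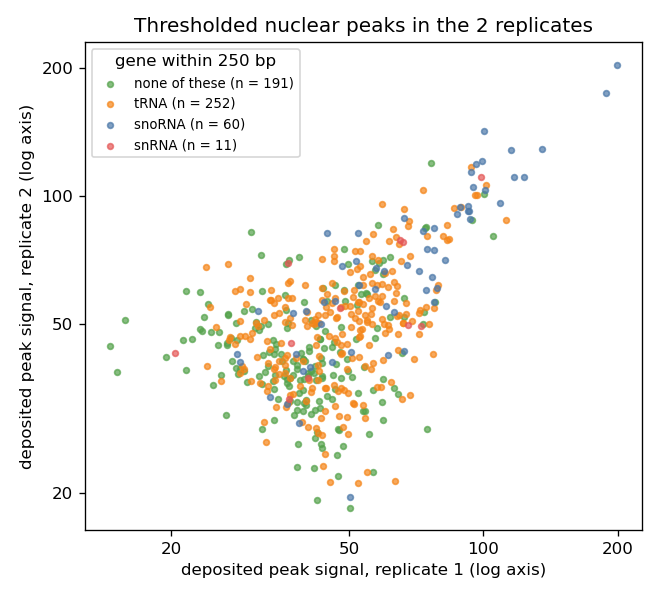
Deposited peak signal in replicate 1 (x axis) and replicate 2 (y axis), both log axes without a stated unit, for thresholded nuclear peaks matched in both, coloured by the small RNA gene within 250 bp. Peaks at snoRNA genes reach the highest values in both replicates, and Spearman's rho over the 514 peaks is 0.427.

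The strongest nuclear peaks lay at genes for small nucleolar RNAs, which guide the modification of other RNAs. Of the 20 strongest peaks, 7 were mitochondrial, 11 lay at snoRNA genes and 2 at tRNA genes. The strongest nuclear peak, at chromosome V 8500411 to 8500705, had a signal of 403.7 (199.1 in replicate 1 and 203.2 in replicate 2) at the snoRNA gene ZK994.7 (WBGene00044958), in an intron 5681 bp from the nearest protein-coding start, that of pxn-1. The next, at V 12303509 to 12303733, had a signal of 364.0 (188.5 and 174.7) at the snoRNA gene C51F7.4 (WBGene00219860), in an intron with F55C5.17 as the nearest start. Signals of 263.0, 245.2 and 241.5 followed, all outside protein-coding genes, at W03C9.9 (II 11960738 to 11960899, nearest start W03C9.1), ZK265.10 (I 8259454 to 8259627, sre-23) and T19B4.8 (I 5706933 to 5707061, pamn-1). Their replicate values were 135.3 and 128.6, 100.6 and 141.6, and 115.5 and 127.9. The remaining 6 snoRNA peaks, at T03F7.8 (cutl-18), B0334.12 (twk-5), C27H6.5 (unc-41), T06C12.16 (str-56), T02E1.9 (T02E1.2) and W01C9.6 (glb-27), had signals from 203.6 to 238.0, with 93.9 to 123.3 in replicate 1 and 103.2 to 120.3 in replicate 2. The tRNA peaks were both on X and outside protein-coding genes, at the leucine tRNA gene C04A11.t1 (X 13665350 to 13665789, signal 207.7, replicates 101.2 and 105.8, nearest start C04A11.5) and the glycine tRNA gene M02F4.t1 (X 3035917 to 3036356, 207.5, 93.9 and 116.5, M02F4.2). Among the 50 strongest nuclear peaks, 25 were at snoRNA genes, 18 at tRNA genes, 1 at an snRNA gene and 6 at none of these.

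Across all nuclear peaks, tRNA genes were the leading class. A tRNA gene lay within 250 bp of 269 of the 550 summits (48.9%, 44.7 to 53.2), against a mean of 0.402% and a highest value of 4.73% after shifts (permutation p = 0.0002). These summits marked 303 of the 612 nuclear tRNA genes (49.5%, 45.5 to 53.5). snoRNA genes lay at 62 summits (11.3%, 8.75 to 14.2), which marked 63 of 346 genes, and snRNA genes, whose products act mainly in splicing, at 13 summits (2.36%), which marked 10 of 129 genes (permutation p = 0.0002 for each). No summit lay at the 20 rRNA genes annotated, which allows a share of up to 16.8% of them. miRNA genes lay at 4 summits (0.727% against 0.156%, permutation p = 0.0258) and piRNA genes at 10 (1.82% against 3.52%, permutation p = 0.0136). Genes of the biotype ncRNA lay at 234 summits (42.5% against 4.52%, permutation p = 0.0002), and lincRNA genes, antisense RNA genes and pseudogenes at 3, 3 and 14 (permutation p = 0.56, 0.0942 and 0.184). A summit could count in several of these 10 classes, which were not adjusted for one another. Only 208 summits lay away from small RNA genes, so some of the 234 at ncRNA genes were also at small RNA genes. In the strongest 557 peaks of each replicate alone, the share at tRNA genes was 42.1% ± 1.52 (SD, n = 2) and that at snoRNA genes 11.3% ± 0.228 (SD, n = 2). In the 275 stronger peaks the share of peaks at tRNA genes was 57.5%, and these fewer summits marked 29.2% of the tRNA genes.

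**Figure D2:**
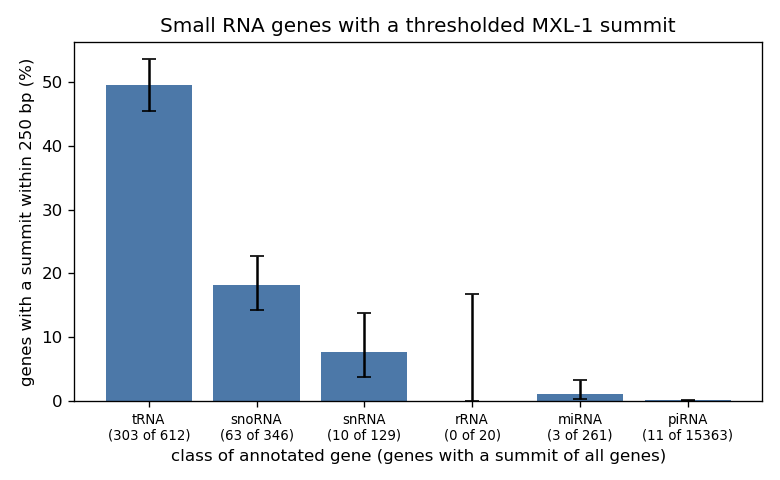
Share of annotated nuclear genes of each class (y axis, percent) with a thresholded summit within 250 bp, with exact 95% binomial intervals as error bars and the counts under each class. tRNA genes stand highest at 49.5%, followed by snoRNA genes at 18.2%, and piRNA genes lie at 0.0716%.

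Peaks at these genes were also stronger than the other nuclear peaks. The median signal was 134.1 at snoRNA genes, 94.5 at tRNA genes and 80.04 at the 208 peaks away from small RNA genes (permutation p = 1e-05 for either class against the last, the smallest that 100000 resamples can give). The order was the same in replicate 1, with medians of 66.4, 48.0 and 40.0, and in replicate 2, with 67.8, 50.2 and 41.9. The classes were chosen after the strongest peaks had been seen, so these tests are a description and no independent support. The replicates make up the pooled signal and are no separate check. Summits at tRNA genes lay a median of 28 bp downstream of the gene's start (quartiles 2 and 64 bp), and 23.05% lay upstream. At snoRNA genes 69.4% of summits (56.3 to 80.4) lay upstream of the start. Of 21 tRNA families, 20 had at least 1 bound gene, from 28.6% of phenylalanine to 70.6% of alanine genes, and selenocysteine tRNA had 0 of 1. No family differed from the others after adjustment by Fisher's exact test, and 1, alanine, had an unadjusted p under 0.05 (p = 0.0134, adjusted p = 0.282).

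Summits were more frequent in promoter windows and less frequent in coding exons than shifted summits. Promoter windows held 186 of 550 summits (33.8%, 29.9 to 37.9, against 25.3% after shifts; permutation p = 0.0002), and 290 (52.7%) lay outside protein-coding genes, against 38.2% (permutation p = 0.0002). Coding exons held 40 (7.27% against 23.8%, permutation p = 0.0002) and 3'UTRs 29 (5.27% against 3.36%, permutation p = 0.028). Introns held 183 (33.3% against 33.3%, permutation p = 1) and 5'UTRs 8 (1.45% against 1.41%, permutation p = 1). The intron share departed in opposite directions in the classes of peaks, at 43.9% of the 342 at small RNA genes (against 32.9%, permutation p = 0.0004) and 15.9% of the 208 away from them (against 33.99%, permutation p = 0.0002). The 208 peaks away from small RNA genes lay in promoter windows in 45.2% of cases (38.3 to 52.2, against 26.0%, permutation p = 0.0002), and the 342 at small RNA genes in 26.9% (against 24.9%, permutation p = 0.434). The promoter share was 54.2% against 45.2% after shifts with the window from 2000 bp upstream to 500 bp downstream, and 22.9% against 15.9% with that from 500 bp upstream to 200 bp downstream (permutation p = 0.002 for each).

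Chromosome X carried more peaks than its share of protein-coding genes, and chromosomes V and II fewer. X held 166 of 550 peaks (30.2%, 26.4 to 34.2) against 13.7% of genes (exact binomial adjusted p = 1.1e-22). V held 72 (13.1% against 25.004%, exact adjusted p = 2.17e-11) and II 70 (12.7% against 17.3%, adjusted p = 0.00797). I, III and IV did not pass the test, with 71, 80 and 91 peaks. The call for II was lost in the 275 stronger peaks, at the same share of fewer peaks (12.7% against 17.3%, exact adjusted p = 0.0921). It was also lost against chromosome length (12.7% against 15.2%, exact adjusted p = 0.218), without peaks at small RNA genes (14.9%, exact adjusted p = 0.614) and without peaks at tRNA genes (17.1%, exact adjusted p = 1). III passed in replicate 1 alone (17.2% against 13.2%, exact adjusted p = 0.0101). Of the peaks at small RNA genes, 138 of 342 (40.4%) were on X. Away from them, X held 28 of 208 (13.5%, 9.14 to 18.9, exact adjusted p = 1), V 30 (14.4%, exact adjusted p = 0.00173) and III 41 (19.7%, exact adjusted p = 0.03). X also carries 276 of the 612 tRNA genes (45.1%), and a summit marked 157 of these (56.9%) against 146 of 336 on the autosomes (43.5%; Fisher's exact p = 0.00114). For snoRNA genes the shares were 1 of 33 on X and 62 of 313 on the autosomes (3.03% and 19.8%, Fisher's exact p = 0.0158).

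**Figure D3:**
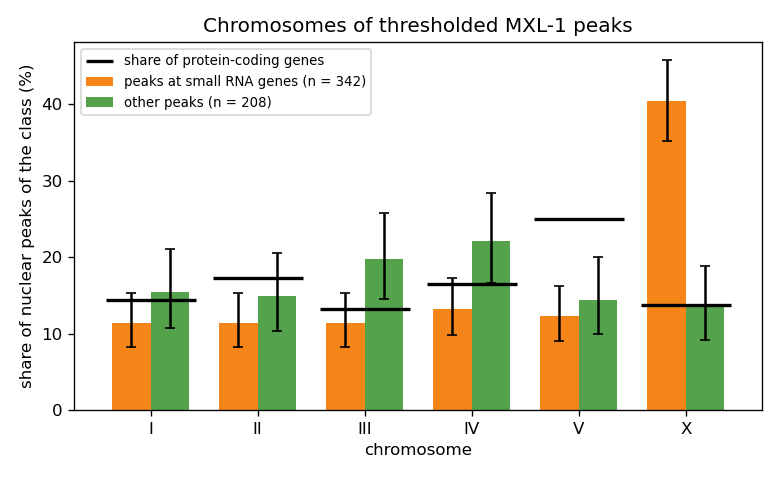
Share of thresholded nuclear peaks on each chromosome (y axis, percent) for peaks at small RNA genes and for other peaks, with exact 95% binomial intervals and a black line at the chromosome's share of protein-coding genes. Peaks at small RNA genes stand at 40.4% on X, and the other peaks at 13.5%.

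Max family dimers bind CACGTG, so its presence at summits was asked next. It lay within 100 bp of 34 of 550 summits (6.18%, 4.32 to 8.53), and in 6.33% of summit windows against 3.54% of their paired flanks (exact McNemar p = 0.0444). This call was lost within 50 bp (3.13% against 1.47%, exact p = 0.0931), within 250 bp (12.02% against 8.97%, exact p = 0.121), in the 275 stronger peaks (4.81% against 3.70%, exact p = 0.678), in replicate 1 alone (difference 2.26 points, exact p = 0.155) and in replicate 2 alone (0.743 points, exact p = 0.665). The 550 strongest pooled peaks over 500 bp from a thresholded summit held CACGTG at 8.00% (Fisher's exact p = 0.29 against the thresholded peaks). Away from small RNA genes 25 of 208 summits had it (12.02%, 7.93 to 17.2), or 12.1% of windows against 3.40% of flanks (exact McNemar p = 0.00143), and at small RNA genes 9 of 342 (2.63%, 1.21 to 4.94; Fisher's exact p = 1.52e-05 between classes). Away from small RNA genes the weaker pooled peaks had it at 9.23%, and the difference of 2.79 points was not detectable (Fisher's exact p = 0.27).

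Among all 6-mers, CGAACC and GTTCGA led, both part of box B, the conserved promoter element inside tRNA genes. CGAACC was in 38.7% of summit windows and 4.28% of flanks (Fisher's exact adjusted p = 4.72e-66), and GTTCGA in 43.5% and 8.94% (adjusted p = 1.05e-53). By the same exact test 481 6-mers were more and 270 less frequent at summits, and CACGTG ranked 670 (adjusted p = 0.0273). Away from small RNA genes 64 were more and 19 less frequent. CGCGCA led there, at 19.2% against 3.16% (exact adjusted p = 1.55e-07), followed by CACTGC at 17.3% against 3.40% (adjusted p = 8.27e-06), and CACGTG ranked 18 (adjusted p = 0.00184). Among the 10 E-box classes CANNTG, adjusted over the 10, CACATG led over all peaks, at 12.5% of summit windows against 6.52% of flanks (exact adjusted p = 0.000723), before CACGTG (exact adjusted p = 0.044). At small RNA genes CACATG was more frequent (17.0% against 6.95%, exact adjusted p = 1.86e-05) and CAATTG less frequent (4.68% against 10.7%, exact adjusted p = 0.00631). There 461 of all 6-mers were more frequent at summits, and CACATG ranked 207. Away from small RNA genes CACGTG and CAAGTG were more frequent (exact adjusted p = 0.000168 and 0.0121). CACATG was not (5.29% against 5.83%, exact adjusted p = 0.951).

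**Figure D4:**
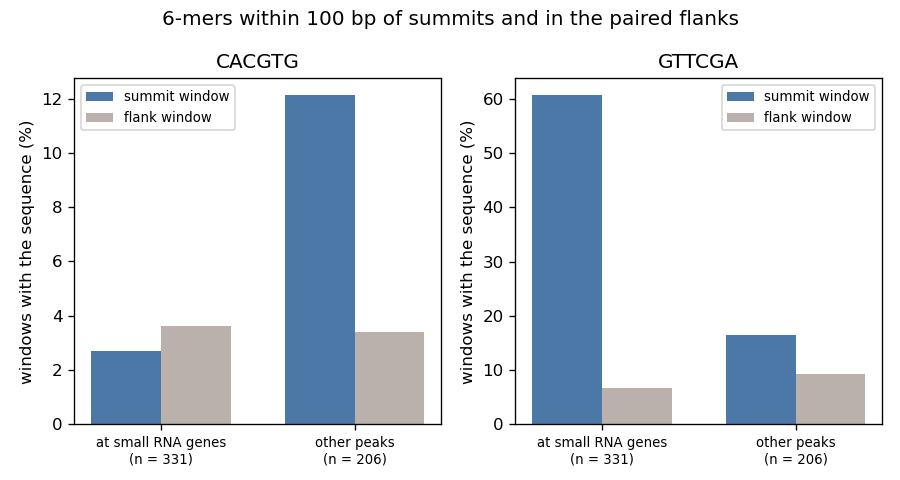
Share of summit windows and of paired flank windows (y axes, percent, 100 bp either side) that hold CACGTG or GTTCGA, for peaks at small RNA genes and for other peaks. CACGTG stands at 12.1% in summit windows of other peaks against 3.40% in their flanks, and GTTCGA at 60.7% in summit windows at small RNA genes against 6.65%.

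Peaks with and without CACGTG did not differ detectably in strength. The median signal was 83.7 with the sequence and 91.1 without it (permutation p = 0.0788), and away from small RNA genes 80.5 and 79.9 (permutation p = 0.658). With a window of 250 bp the medians were 79.0 and 91.8 (permutation p = 0.0033). A T directly 5' of CACGTG stood at 19 of 37 sites in summit windows (51.4%, 34.4 to 68.1) and 2077 of 4881 other promoter sites (42.6%; Fisher's exact p = 0.318). Few of the genome's CACGTG sites were near a summit, 11 of 4892 in promoter windows (0.225%, 0.112 to 0.402), 12 of 3581 in introns (0.335%), 10 of 3664 outside genes (0.273%) and 3 of 5232 in coding exons (0.0573%), the last 3 classes outside promoter windows. With all pooled peaks the promoter share was 5.21%. The number of summits limits these shares, and they were not set against a chance level.

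Genes for cytosolic ribosomal proteins were bound more often than other genes, and genes of the chemoreceptor list less often. A summit lay in the promoter window of 212 of 19973 protein-coding genes. Of 81 ribosomal protein genes 5 were bound (6.17%, 2.03 to 13.8, against 1.04% of other genes; Fisher's exact adjusted p = 0.0393). They were rpl-3 (WBGene00004414, III 3867309 to 3867748, signal 158.7, replicates 74.1 and 83.8), rpl-15 (WBGene00004427, IV 654709 to 655148, 104.1, 65.8 and 42.7), rla-1 (WBGene00004409, I 2069167 to 2069606, 97.7, 52.0 and 55.2), rpl-35 (WBGene00004449, III 7854477 to 7854916, 95.1, no matched peak in replicate 1 and 51.7 in replicate 2) and rpl-22 (WBGene00004434, II 5055153 to 5055592, 82.6, 45.8 and 33.2). The last, rpl-22, was named after its value was seen. No small RNA gene lay at these 5 peaks, and none of the 5 had CACGTG within 100 bp. The chemoreceptor list was meant to hold genes for receptors of sensory neurons. It took symbols that begin with sr, whatever the product, and left out symbols such as str-56. Of its 1171 genes, 3 were bound (0.256%, 0.0529 to 0.747, against 1.11%, exact adjusted p = 0.0393), and each of these peaks lay at a small RNA gene. They were sre-23 (signal 245.2, at a snoRNA gene), srh-269 (96.1, replicates 45.9 and 55.8) and srd-44 (90.2, 48.0 and 42.5), the last 2 at tRNA genes. Both calls were lost when only the 4595 genes with any pooled peak in their promoter window were compared, with 9.43% of ribosomal protein genes bound against 4.56% of the others and 2.24% of chemoreceptor genes against 4.69% (exact adjusted p = 1 for both). The chemoreceptor call was also lost with the promoter window from 500 bp upstream (0.171% against 0.723%, odds ratio 0.235 and 0.228 with the main window, 138 genes bound) and in the 275 stronger peaks (0.171% against 0.527%, odds ratio 0.323, 101 genes bound), while the window from 2000 bp upstream gave 17.3% of ribosomal protein and 0.598% of chemoreceptor genes, and assignment to the nearest start 14.8% and 0.769%, all past the threshold.

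The other 26 lists did not pass the test (adjusted p from 0.309 to 1). Autophagy genes had 2 of 27 bound, lgg-2 (IV 10935995 to 10936434, signal 75.9, replicates 27.9 and 50.2) and lgg-1 (II 6347664 to 6348103, 72.0, 31.8 and 49.4), which encode the worm's Atg8-type proteins (exact unadjusted p = 0.0331, adjusted p = 0.309). Respiratory chain genes had 2 of 47, nduf-9 (141.6, 58.0 and 85.2) and cox-6A (114.6, 72.6 and 49.4), the latter peak at an snRNA gene. In the strongest 557 peaks of replicate 2 alone both lists passed, with 3 of 27 autophagy genes (11.1%, exact adjusted p = 0.0219) and 5 of 47 respiratory chain genes (10.6%, exact adjusted p = 0.00372). In those of replicate 1 alone neither passed, with 0 of 27 (exact adjusted p = 1) and 2 of 47 (4.26%, exact adjusted p = 0.583). Detoxification genes had 2 of 185, cyp-43A1 (196.7, 95.6 and 100.2) and gst-27 (134.1, 52.3 and 81.7), innate immunity 2 of 312, clec-126 (119.6, 57.8 and 61.7) and spp-26 (93.1, 49.6 and 44.8), and nuclear hormone receptors 2 of 269, nhr-255 (104.6, 60.0 and 49.96) and nhr-1 (70.9, unmatched in replicate 1 and 27.4 in replicate 2). All but nhr-1 of these 6 peaks lay at small RNA genes. A single gene was bound in 9 lists. These were mitochondrial ribosomal proteins (mrpl-23, 162.9, 77.6 and 84.0), V-ATPase and lysosome (cpr-9, 113.7, 55.5 and 57.3), homeobox factors (ceh-2, 98.6, 36.9 and 62.9), cuticle collagens (col-185, 91.8, 50.7 and 41.5), neuropeptides (flp-23, 76.3, 30.04 and 45.9), aminoacyl-tRNA synthetases (ears-2, 76.2, 36.3 and 36.2), heat shock and chaperones (cct-8, 74.3, 34.1 and 37.9), glycolysis (hxk-2, 72.0, 31.4 and 37.6), and cell cycle and DNA replication (cdc-5L, 70.0, 36.9 and 32.9). The first 5 of these peaks lay at small RNA genes. None of the peaks named here for the 26 lists had CACGTG within 100 bp. None was bound in 12 lists, which were the Max network, translation factors, nucleolus and ribosome biogenesis, proteasome, lipid metabolism, methionine and folate cycles, insulin pathway and longevity factors, histones, yolk proteins, germ granules and oocyte regulators, major sperm proteins, and muscle.

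None of the 6 Max network genes, mxl-1, mxl-2, mxl-3, mdl-1, mml-1 and hlh-30, had a thresholded summit in its promoter window, and 0 of 6 allows a share of up to 45.9%. In the pooled list mdl-1 (WBGene00003163, X 6742351 to 6743899), the gene of MXL-1's partner, had 2 summits with a strongest signal of 45.5 (21.2 in replicate 1 and 30.8 in replicate 2), ranked 1794 of 14193 nuclear peaks. A thresholded peak lay within mdl-1 outside that window, in a coding exon 977 bp from the start (X 6743108 to 6743547, signal 72.7, replicates 19.4 and 41.7, rank 463 of 550), so that 1 of 6 genes was bound when summits were assigned to the nearest start (exact adjusted p = 0.405). hlh-30, the worm's TFEB gene, had 4 with a strongest signal of 31.4 (19.3 and 19.5). mxl-3 and mml-1 had summits in replicate 2 alone (24.6 and 14.9), and mxl-2 had none in any list. At the genes present in the transgene, mxl-1 had no summit in its promoter window in any list, and unc-119 had 1 in replicate 1 alone (signal 15.7).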

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

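The test of shared copies, that of CACGTG, that of ribosomal protein promoters and that of tRNA genes on X were set down before their results were seen, and the split by small RNA genes that they use was chosen after the peaks had been seen.

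The 7 thresholded peaks on the mitochondrial chromosome are a signal on a chromosome that the comparisons above do not use. They include the 6 strongest peaks of the list, with signals from 531.3 to 3434. The strongest has 1670 in replicate 1 and 1753 in replicate 2 and covers M 4484 to 5083, at the genes MTCE.20 (tRNA) and MTCE.21.1 (protein-coding), an interval listed with 2 summits. The others lie at ND1, MTCE.7 (rRNA) and MTCE.12.1, and the weakest, at ND1 with a signal of 290.3, has no matched peak in replicate 1. No explanation was tested for them.

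A first pattern is the concentration of peaks at tRNA and snoRNA genes. Reads shared between identical annotated copies are argued against as the whole of it. Of the 489 genes with a sequence unlike any other annotated tRNA or snoRNA gene, 22.7% carried a summit (19.1 to 26.7). The highest circular shift gave 4.50%. Of these 489 genes, 346 were snoRNA genes, with 18.2% marked. Near-identical copies, and summits of a neighbouring gene within 250 bp, were not set apart, so the test does not exclude reads shared between similar sequences. The share was 54.4% (49.7 to 58.9) of tRNA genes with an identical copy and 33.6% (25.9 to 41.9) of tRNA genes without, so shared reads may still add to it. MXL-1 binding to CACGTG beside these genes is argued against by the 2.73% of their summits with the sequence (1.25 to 5.11), against 3.45% of paired flanks. Accessibility of highly transcribed genes stays open: ribosomal protein promoters were bound 5.93 times as often as other promoters, which met the ratio of 3 set in advance, but the interval of 1.96 to 13.3 includes smaller ratios, the shares were 9.43% and 4.56% (odds ratio 2.18) among promoters with any pooled peak, and no accessibility data or untagged control was used here.

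A second pattern is the excess on X. Of the 281 peaks more than 250 bp from any tRNA gene, 10.3% were on X (7.02 to 14.5), an interval that includes the 13.7% of protein-coding genes, so the tRNA genes lying on X could account for the excess. The higher bound share of tRNA genes on X than on autosomes is not covered by that test, and no biological explanation was tested.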

How the results depend on the processing

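Replicate agreement, the share of peaks at small RNA genes, the share of tRNA genes with a summit, the promoter share and the comparison of bases beside CACGTG kept their direction and side of the threshold under every alternative run, with ranges of 37.9 to 61.9%, 55.0 to 78.2%, 29.2 to 50.98%, 22.9 to 54.2% and 3.88 to 11.4 percentage points. Over all results 53 of 73 alternatives were counted as unchanged. Counts without a test were so counted when they stayed within 1.5 times the main count. The chromosome distribution was counted on X alone, so the changed calls for II and III given above do not enter. The 53 include the signal difference by CACGTG away from small RNA genes, which changed sign while neither value passed the threshold. Leaving out a replicate does not apply to replicate agreement, and no paired analysis was possible because there was 1 group. Without peaks at small RNA genes, an alternative added after seeing the data, the share on X was 13.5% against 13.7% expected, and 64 6-mers were more frequent in place of 481; fewer peaks were tested there. The excess of CACGTG at summits over its control, 2.79 percentage points, was 1.66 with 50 bp windows (3.13% against 1.47%, where fewer windows held it), 3.05 with 250 bp windows, 1.11 in the 275 stronger peaks, 0.743 to 2.26 without either replicate, all no longer past the threshold, and -1.82 against weaker pooled peaks; the cause was not tested. The signal difference with minus without CACGTG was -12.9 with 250 bp windows, past the threshold, against -7.40. It was -7.18 with 50 bp windows and 0.671 away from small RNA genes. On the replicates' own signal it was -2.41 in replicate 1 alone and -8.18 in replicate 2 alone. None of these 4 passed the threshold. The share of promoter CACGTG sites bound was 0.102% within 50 bp, 0.491% within 250 bp and 5.21% with all pooled peaks, as wider windows and longer lists must give. The 2 gene lists past the threshold became 1 with the promoter window from 500 bp upstream, 1 in the 275 stronger peaks, 0 against genes with any pooled peak, and 2 to 4 without either replicate. Chemoreceptors were no longer past the threshold at 0.171% with that promoter window (0.723% of other genes), 0.171% in the 275 stronger peaks (0.527%) and 2.24% against genes with any pooled peak (4.69%), where ribosomal protein genes stood at 9.43% (4.56%). Fewer genes were bound or compared in each, and the chemoreceptor odds ratios were 0.235, 0.323 and 0.466 against 0.228. Unknown read depth limits all comparisons of signal between lists.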

Other observations

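All tests here were chosen after the results they bear on had been seen, and the genes named were chosen after their values were seen.

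Away from small RNA genes the strongest peaks lay near dhs-8 (II 14496818 to 14497257, signal 193.9), hrg-5 (IV 11025937 to 11026376, 193.8), tasp-1 (III 10759019 to 10759458, 192.3), ints-8 (175.7) and K12H4.5 (161.3), and none of these 5 had CACGTG within 100 bp. The strongest with it lay near gdh-1 (124.5) and bet-2 (124.2). These 208 peaks were more frequent in 3'UTRs than shifted summits, with 29 (13.9%, 9.54 to 19.4, against 3.34%; permutation p = 0.0002). GTTCGA was in 16.5% of their windows and 9.22% of the paired flanks (exact McNemar p = 0.0444).

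Small RNA genes took a falling share down the pooled list, from 83.2% of the 137 strongest nuclear peaks to 18.5% of ranks 551 to 1100 and 1.40% of ranks 4401 to 14193. Away from small RNA genes, CACGTG was at 2 of 23 peaks (8.70%, 1.07 to 28.0) of ranks 1 to 137, 13.5% (4.54 to 28.8) of ranks 138 to 275, 12.2% of ranks 276 to 550, 9.15% of ranks 551 to 1100, 4.87% of ranks 1101 to 2200, 5.58% of ranks 2201 to 4400 and 4.81% of the rest. In the whole pooled list, which includes background, 511 of 612 tRNA genes (83.5%) and 140 of 346 snoRNA genes (40.5%) had a summit within 250 bp.

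Another pattern is CACGTG at the peaks away from small RNA genes. A higher G and C content alone is argued against, as 0 of the 23 other palindromic 6-mers with 4 G or C bases showed a difference between summit and flank as large as its 9.11 points (-3.16 to 2.62). Of the 2079 other 6-mers of any kind 18 did, 6 with 4 and 8 with 5 or 6 G or C bases, among them CGCGCA (19.2% against 3.16%) and the palindrome GCGCGC (11.1% against 1.70%), so sequence context of that kind stays open. Position relative to transcript starts is also argued against, since windows at the same distances from randomly drawn starts held it at 3.37% (2.84 to 3.96) against 12.02% at summits (7.93 to 17.2). A candidate explanation is binding by MXL-1 or another factor that reads CACGTG, which these data cannot separate without a control lacking the tag, and weaker pooled peaks held the sequence at 9.23% (Fisher's exact p = 0.27).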
